A study of Mus musculus with 16 samples.

How the data were processed

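Total RNA of mouse hippocampus was hybridized as biotin-labelled cRNA to 16 Illumina bead arrays, per the labels. The deposited scanner table holds 1 log2 intensity per probe and array, with no normalization between arrays, and its values ran from 6.20 to 15.1. The detection p-value of each probe on each array is deposited beside it, per the file headers. The deposited series matrix holds log2 values that the authors had quantile normalized across the 16 arrays, as found from the values, which kept the rank order of the scanner table (rank correlation 1) and differed from quantile normalized scanner values by at most 0.00713. Partek was used, per the submitters' processing notes, with no version named, and background subtraction and scanner software are not given in the sources used here. In the first array 26 cells of the detection p-value column held text, and these were treated as missing in the filter and interpolated for background correction. Of 45281 probes, 34885 carried 1 gene symbol, 18 several and 10378 none. A RefSeq gene table was used only for names and matched 34807 of 34903 probe entries with a symbol by Entrez ID, with 0 symbols updated.

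The groups and the slide of each array were taken from the labels. Intensities were background corrected and quantile normalized with neqc (offset 16) of limma 3.58.1 in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probes with a detection p under 0.05 on at least 3 arrays were tested, which left 22625 probes, 19006 of them with 1 symbol, for 12020 genes. A linear model with 1 mean per group over the 16 arrays was fitted with limma, with moderated variances, and Benjamini-Hochberg adjusted p under 0.05 over all probes counted as passing. All p-values are two-sided. The 6 comparisons were age in vehicle mice, THC at 12 months, THC at 2 months, the difference of both THC responses, age in THC mice, and old THC against young vehicle mice. The groups, tests, gene lists, named-gene rule and most alternatives were chosen before the data were examined.

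The named-gene rule used 1 probe per gene, the one with the highest mean. For the first 3 comparisons it took the 10 largest rises and 10 largest falls past the threshold or, where fewer than 10 genes passed, all that passed and, as values only, the 10 genes with the smallest p. For the other 3 it took the 5 genes with the smallest p. From each list described it took the 2 members with the smallest p in each direction, and it took Cnr1 in each drug comparison. Gene models without a name were counted only, and 1 gene that the rule took for THC at 12 months is not reported here. Lists with at least 4 tested genes were tested with camera of limma at its preset inter-gene correlation of 0.01, again with an estimated correlation, and adjusted over the 35 lists. The lists were markers of choroid plexus, ependyma, meninges and fibroblasts, thalamus, striatum, neocortex, blood, microglia, astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, endothelium and pericytes, inhibitory neurons, dentate granule cells, CA1 and CA3 and CA2 pyramidal cells, and genes of the endocannabinoid system, synaptic proteins, glutamate receptors, GABA-A receptors, neurotrophins, immediate early genes, histone acetylation, DNA and histone methylation, adult neurogenesis, complement and antigen presentation, interferon response, inflammation, collagens and matrix, cholesterol synthesis, oxidative phosphorylation, heat shock, circadian clock, glucocorticoid response and potassium channels. A list of 12 midbrain dopamine neuron markers, 6 of them tested, was added after the data were seen. Means of list genes were also compared between arrays with an exact two-sided permutation test.

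The fit was tested on simulated arrays with 50 changed probes at each of several sizes. At a log2 change of 0.5 it recovered 14% of them for age in vehicle mice, 6% for THC at 12 months, 4% for THC at 2 months, 10% for age in THC mice and 14% for old THC against young vehicle. At a change of 1 it recovered 76%, 90%, 66%, 80% and 66% in the same order, and at a change of 2 it recovered 100%, 98%, 94%, 100% and 100%. The difference of both THC responses was not part of that test. The simulated noise was drawn separately for each probe and array, with no slide structure. Changes were placed only on probes with a mean log2 value above 6. The recovered shares may therefore be too high for the real arrays and for probes near the background. Alternatives were quantile normalization without background correction, the deposited series matrix values, no filter, a filter at detection p under 0.01 on at least 8 arrays, the slide as a fixed or random block, a mean-variance trend with robust variances, array weights, an adjusted p under 0.1, 1 probe per gene, the arrays of the compared groups alone, the choroid plexus mean as a covariate, no choroid plexus genes, the next brightest probe of a gene, differences within slides and each array left out in turn. Values for a gene not detected on any array of a group are given as bounds on the difference of group means, with no allowance for the spread of arrays.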

Results

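Gene expression was measured in the hippocampus of male C57BL/6J mice on 16 Illumina bead arrays of 45281 probes. Mice aged 2 or 12 months had received vehicle or Δ9-tetrahydrocannabinol (THC), the main psychoactive compound of cannabis, at 3 mg per kg per day for 28 days from a minipump under the skin. They were tested for behaviour between days 33 and 41 and killed on day 46. There were 3 vehicle and 3 THC arrays at 2 months, and 5 vehicle and 5 THC arrays at 12 months. The labels give separate samples, the design text gives 3 to 5 mice per group, and nothing says more about how mice and arrays correspond. Between 41.1% and 45.9% of probes were detected per array, and the median log2 scanner intensity ran from 6.62 to 7.02. Arrays of the same group correlated at Pearson r 0.959 to 0.990 across probes, and the number of arrays limits the precision of each group mean. The arrays came from 4 slides. The 4 arrays of slide 1 lay at −50.2 to −33.7 on the first principal component, which held 32.3% of the variance, and the other 12 arrays lay at −0.87 to 31.3.

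The comparison of 12 with 2 months in vehicle mice asked which genes differ with age without the drug. The complement genes C4a, C4b and C2 had higher mean values at 12 months. C4a and C4b, the C4 genes of the complement cascade, were 1.06 ± 0.21 and 0.74 ± 0.19 higher on the log2 scale (SE, 5 against 3 arrays), which is 2.09-fold and 1.67-fold, with the lowest of 3 C4b probes at 0.10, and C2, another complement component, was 1.36 ± 0.30 higher. Mocs1, an enzyme of molybdenum cofactor synthesis, averaged 7.87 ± 0.10 (SD, n = 5) at 12 months and 7.16 ± 0.11 (SD, n = 3) at 2 months, a difference of 0.71 ± 0.11 or 1.64-fold. Nptx2, a pentraxin secreted at excitatory synapses, was lower at 12 months by a log2 difference of −1.09 ± 0.24, from 9.75 ± 0.24 to 8.66 ± 0.19. Gpr17, a receptor of maturing oligodendrocyte precursors, differed by −0.66 ± 0.15, the axonal adhesion protein gene Ntng1 by 0.81 ± 0.16, and Cp, which encodes ceruloplasmin, by 0.92 ± 0.22. The remaining genes among the 10 with the smallest p were Rnf207 at 0.82 ± 0.18, Rnf24 at −0.76 ± 0.18, with its other probe at −0.00351, and Lacc1 at 0.56 ± 0.13. With quantile normalization alone some sizes were smaller, at 0.68 for C2, 0.49 for Cp, 0.32 for Rnf207, −0.31 for Rnf24 and 0.24 for Lacc1. None of these genes passed the adjusted p of 0.05 over all probes. limma called 0 of 22625 probes, with 1032 at an unadjusted two-sided p under 0.05 where chance alone gives 1131. The smallest adjusted p was 0.0504, for a probe without a gene symbol at 0.91, and Mocs1 had an adjusted p of 0.081, C4a 0.396 and Nptx2 0.557. Within the 3 slides that held both ages, Mocs1 differed by 0.70, 0.81 and 0.56, C4a by 0.93, 1.29 and 1.05, and Nptx2 by −0.91, −1.07 and −1.25. With the slide as a block, 2 probes passed, Mocs1 at 0.71 (adjusted p = 0.0477) and the probe without a symbol. In that fit 1968 probes had an unadjusted p under 0.05, above the 1131 of chance, so this count depends on the slide term. The adjusted p of Mocs1 ran from 0.00706 to 0.245 over some of the alternatives. These were quantile normalization alone, the series matrix values, the slide as a fixed or random block, and the choroid plexus covariate. The count was 3 with quantile normalization alone and with the deposited series matrix values, and 1 without control_Old replicate 3.

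**Figure D1:**
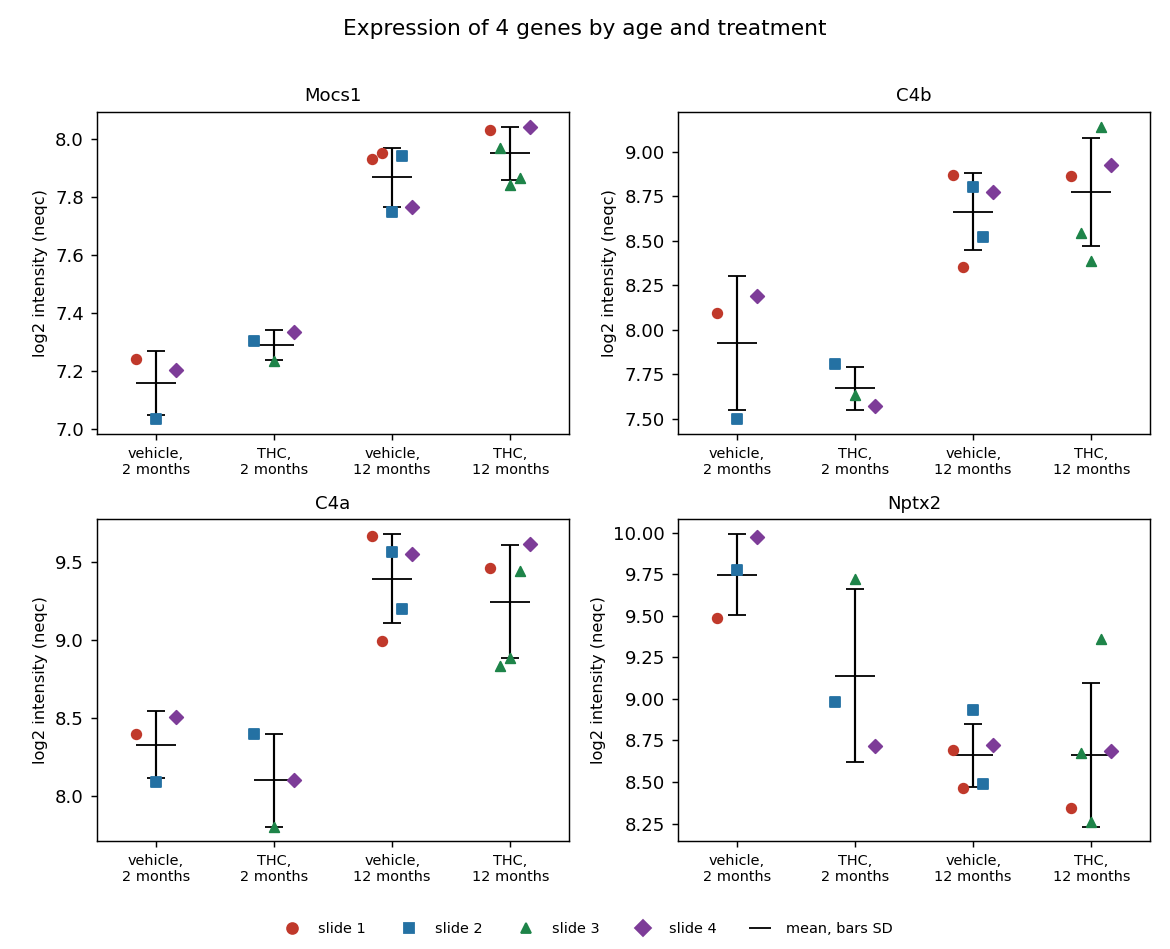
Normalized log2 expression of Mocs1, C4b, C4a and Nptx2 on each array by age and treatment, with point shapes for the slides and bars for the group mean and SD (3 or 5 arrays). Mocs1 averaged 7.87 in vehicle and 7.95 in THC mice at 12 months, and 7.16 and 7.29 at 2 months.

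Among the gene lists, markers of blood and meninges were higher at 12 months in vehicle mice, and markers of myelin, oligodendrocyte precursors and CA3 and CA2 pyramidal cells were lower. All 5 blood genes were higher, with a median log2 difference of 1.06 (camera adjusted p = 3.97e-09), and adjusted over the list alone 5 of them passed, among them the hemoglobin genes Hbb-bs at 1.10 ± 0.29 and Hbb-bt at 1.04 ± 0.29. For blood the adjusted p = 0.208 with an estimated correlation. Meningeal and fibroblast markers were higher for 11 of 12 genes, with a median of 0.87 (adjusted p = 6.63e-08, and adjusted p = 0.214 with an estimated correlation), and 5 passed adjusted over the list alone, including the proteoglycan gene Bgn at 0.96 ± 0.23 and the retinoic acid enzyme gene Aldh1a2 at 0.94 ± 0.23, with its other probe at 0.11. The complement and antigen presentation list was higher for 15 of 19 genes, with a median of 0.10 (adjusted p = 0.00204, and adjusted p = 0.269 with an estimated correlation). Adjusted over the list alone 2 of its genes passed, C4a (adjusted p = 0.00199) and C4b (adjusted p = 0.0120). Its call ended without control_Young replicate 1 (0.05, adjusted p = 0.164) and without control_Young replicate 2 (0.09, adjusted p = 0.0607), and its median was 0.29 without control_Young replicate 3 and 0.20 without control_Old replicate 2. Myelin markers were lower for 11 of 12 genes, with a median of −0.40 (adjusted p = 5.72e-05, and adjusted p = 0.352 with an estimated correlation), Opalin at −0.83 ± 0.32 and Cnp at −0.73 ± 0.28, with its other probe at −0.24. All 9 precursor markers were lower, with a median of −0.10 (adjusted p = 0.00506, and adjusted p = 0.269 with an estimated correlation), and Gpr17 passed adjusted over the list alone (adjusted p = 0.00463). The precursor median was −0.30 without control_Young replicate 3, −0.20 without control_Young replicate 2, −0.16 without control_Young replicate 1, and −0.17 without control_Old replicate 1 or 2. All 10 CA3 and CA2 markers were lower, with a median of −0.48 (adjusted p = 0.000273, and adjusted p = 0.269 with an estimated correlation), among them the kainate receptor gene Grik4 at −0.46 ± 0.19, and this call ended without the 4 arrays of slide 1 (−0.34, adjusted p = 0.0772). Without control_Young replicate 2 the CA3 and CA2 median was −0.28 (adjusted p = 0.0392). Within slides the medians ran from 0.13 to 2.24 for blood, from 0.28 to 1.36 for meninges, from 0.09 to 0.24 for complement, from −0.72 to −0.18 for myelin, from −0.52 to −0.18 for precursors and from −0.72 to −0.42 for CA3 and CA2 cells.

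Markers of tissue next to the hippocampus and further lists also differed with age in vehicle mice. Choroid plexus markers were lower for 18 of 19 genes, with a median of −0.995 (adjusted p = 1.57e-06, and adjusted p = 0.455 with an estimated correlation), and Ttr, which encodes transthyretin, differed by −4.87 ± 1.88. Without control_Young replicate 2 the choroid plexus median was 0.01 (adjusted p = 1.00). Without control_Young replicate 3 it was −1.53, and within slides it ran from −2.66 to −0.0311. Ependyma markers had a median of −0.58 (adjusted p = 0.000723, and adjusted p = 0.269 with an estimated correlation), and without control_Young replicate 2 one of −0.29 (adjusted p = 0.145). All 10 thalamus markers were higher, with a median of 0.72 (adjusted p = 3.48e-05, and adjusted p = 0.269 with an estimated correlation), and the vesicular glutamate transporter gene Slc17a6 differed by 1.27 ± 0.50. All 9 striatum markers were lower, with a median of −0.29 (adjusted p = 0.00118, and adjusted p = 0.360 with an estimated correlation), and without control_Young replicate 2 the call ended (−0.25, adjusted p = 0.328). The striatum median was −0.57 without control_Young replicate 1 and −0.45 without control_Old replicate 4. Neocortex markers had a median of 0.38 (adjusted p = 0.00860, and adjusted p = 0.455 with an estimated correlation), with the call ended by leaving out control_Young replicate 2 (0.13, adjusted p = 0.490) or control_Old replicate 5 (0.23, adjusted p = 0.119). Astrocyte markers were higher for 10 of 11 genes, with a median of 0.12 (adjusted p = 0.0122, and adjusted p = 0.269 with an estimated correlation), Gfap at 0.23 ± 0.17, and the call ended without control_Young replicate 1, control_Young replicate 2 or control_Old replicate 3, with medians of 0.16, 0.11 and 0.11 and adjusted p between 0.115 and 0.140. Heat shock genes were lower for 14 of 17 genes, with a median of −0.19 (adjusted p = 0.00297, and adjusted p = 0.360 with an estimated correlation), and the call ended without control_Old replicate 2 (−0.10, adjusted p = 0.0615) or without slide 1 (−0.14, adjusted p = 0.411). The heat shock median was −0.32 without control_Young replicate 1 and −0.10 without control_Young replicate 2. Within slides the medians ran from −1.36 to −0.24 for ependyma, from 0.12 to 1.01 for thalamus, from −0.93 to −0.0434 for striatum, from 0.0771 to 1.02 for neocortex, from −0.11 to 0.28 for astrocytes and from −0.33 to 0.0224 for heat shock genes. With the choroid plexus mean as a covariate the calls of striatum (−0.18, adjusted p = 0.344), neocortex (0.20, adjusted p = 0.624), oligodendrocyte precursors (−0.11, adjusted p = 0.0569) and CA3 and CA2 cells (−0.14, adjusted p = 0.102) ended. In all 13 of 35 lists passed at the preset correlation, 14 with the slide as a block, where the circadian clock was added (0.14, adjusted p = 0.0456), 7 without control_Young replicate 2 and 0 with an estimated correlation. An exact two-sided permutation test of list means between arrays gave 5 lists under 0.05, at a smallest p of 0.0179 that is also the smallest it can give, and 0 after adjustment.

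**Figure D2:**
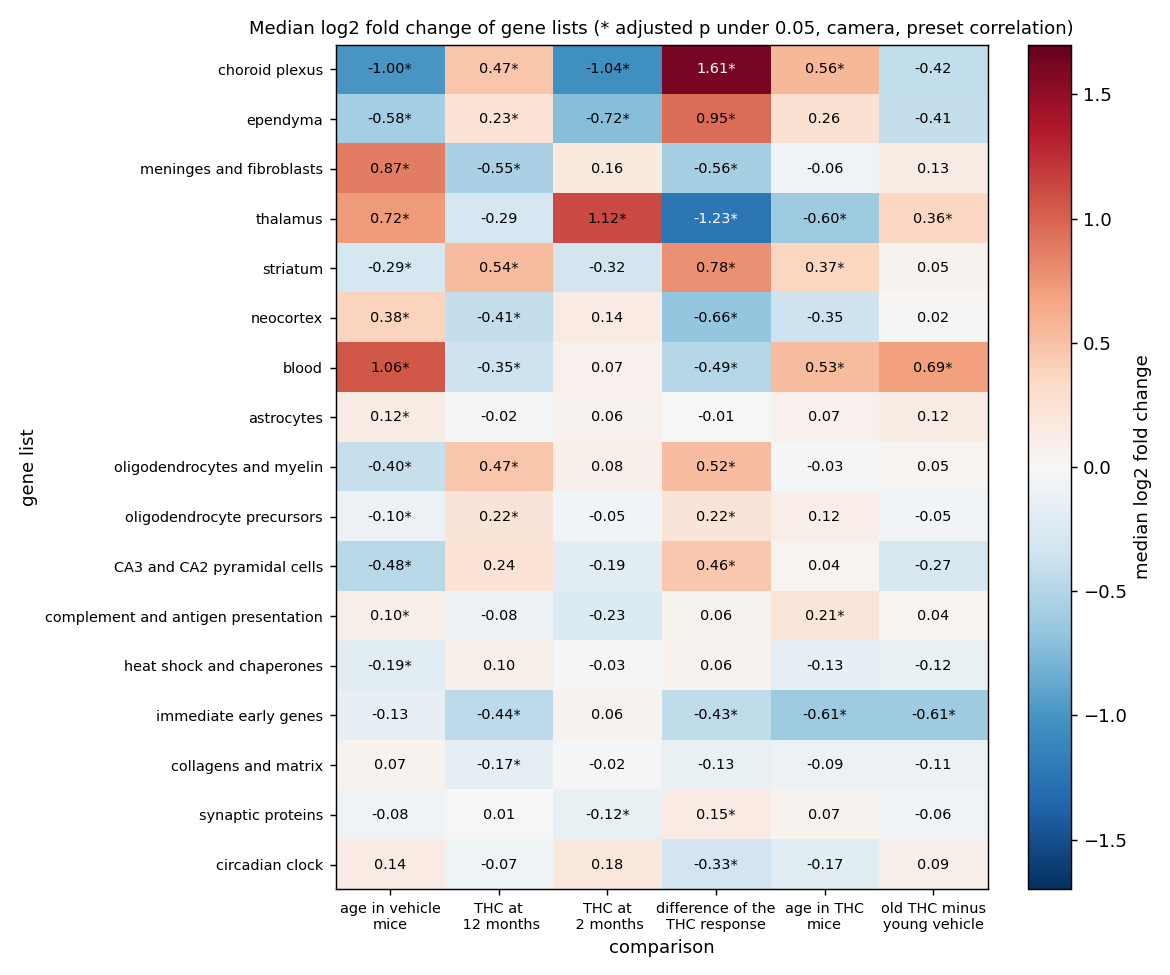
Median log2 difference of the listed genes (color scale) for 17 gene lists in the 6 comparisons, with a star where the camera adjusted p at the preset correlation was under 0.05. Blood (1.06) was among the lists that were higher with age in vehicle mice, and choroid plexus (−0.995) among those that were lower.

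The comparison of THC with vehicle at 12 months addressed the effect of the drug in the older mice, the main question named in the series title. The named genes with the smallest p were mostly lower after THC. Ifitm2, an interferon-induced membrane protein, differed by −0.56 ± 0.12 (log2, SE, 5 against 5 arrays), the transcription factor gene Foxc1 by −0.75 ± 0.17, Fxyd5, a regulator of the sodium pump, by −0.99 ± 0.23, and Tnfrsf11b, which encodes osteoprotegerin, by −1.02 ± 0.24. Myl9, a myosin light chain of smooth muscle, differed by −0.59 ± 0.15, Hdhd5 by −0.54 ± 0.13 and Ntng1 by −0.55 ± 0.14, where 1 of the other 3 Ntng1 probes went the opposite way at 0.0827. Higher values were found for Bet1, a transport protein of the Golgi, at 0.53 ± 0.13 and for the Ras-related Rasd1, which was detected on 1 of 5 vehicle and 4 of 5 THC arrays, so no size is given. With quantile normalization alone Foxc1 was at −0.37, Tnfrsf11b at −0.40, Myl9 at −0.34 and Bet1 at 0.23, and the next brightest Fxyd5 probe was at −0.47. Cnr1, the CB1 cannabinoid receptor through which THC acts on neurons, averaged 5.99 ± 0.31 (SD, n = 5) after THC and 5.76 ± 0.40 (SD, n = 5) after vehicle, a difference of 0.23 ± 0.19. The 1 tested Cnr1 probe was dim, with means from 5.36 to 5.99 over all groups. The simulated changes were placed only above a mean of 6, so recovery at its level was not tested. The Cnr1 difference was 0.0561 with the slide as a block, 0.09 with quantile normalization alone, 0.0622 without control_Old replicate 4 and 0.10 without THC_Old replicate 2. These 10 genes had an adjusted p of 0.916. limma called 0 of 22625 probes, with 1080 at an unadjusted p under 0.05, and with the slide as a block 31 probes, with 2605 at an unadjusted p under 0.05. Within the 2 slides that held both groups, each with 1 old THC array, Ifitm2 differed by −0.58 and −0.65, Fxyd5 by −1.12 and −2.19, and Cnr1 by 0.13 and −0.48. The 31 probes of the block fit, chosen after their values were seen, were 23 higher and 8 lower, among them the serine protease gene Klk6 at 2.04 (adjusted p = 0.0124, and 0.46 with adjusted p = 0.927 without the block), the dopamine receptor gene Drd2 at 1.37 and the dopamine transporter gene Slc6a3. Slc6a3 was detected on 0 of 5 vehicle and 2 of 5 THC arrays at 12 months. Its group mean was at least 1.52-fold higher after THC without the block, with a limma adjusted p of 0.916. That mean rests on THC_Old replicates 1 and 5, at 6.53 and 7.21. The other old THC arrays lay at 4.47 to 4.61, and the old vehicle arrays at 4.49 to 4.80. The count of probes in the block fit was 0 without THC_Old replicate 1 and 1 without control_Old replicate 1. It was 2 without control_Old replicate 2 and without THC_Old replicate 5. It was 5 without control_Old replicate 5 and 151 without THC_Young replicate 2. It was 129 without THC_Young replicate 1, 67 without control_Old replicate 3, and 53 without control_Young replicate 2 and without THC_Old replicate 3.

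Among the lists, myelin and striatum markers were higher after THC at 12 months, and meningeal markers and immediate early genes were lower. The old vehicle arrays enter this comparison and that of age in vehicle mice with opposite sign. List shifts opposite to those of age can therefore arise without an effect of the drug. All 12 myelin markers were higher, with a median log2 difference of 0.47 (adjusted p = 3.28e-07, and adjusted p = 0.338 with an estimated correlation), and Opalin was 0.83 ± 0.27 and Mobp 0.66 ± 0.27 higher. The median was 0.96 with the slide as a block and ran from 0.57 to 0.89 within slides. Each slide that held both groups had 1 old THC array, replicate 1 on slide 1 and replicate 5 on slide 4. All within-slide values of this comparison rest on these arrays. Their striatum means were 8.37 and 7.89, against 6.98 to 7.20 on the other old THC arrays. Their choroid plexus means were 7.81 and 8.09, against 5.39 to 5.67. All 9 striatum markers were higher, with a median of 0.54 (adjusted p = 3.29e-06, and adjusted p = 0.338 with an estimated correlation), and the dopamine receptor gene Drd2 differed by 0.69 ± 0.30, with a list median of 1.10 with the slide as a block and of 1.11 and 1.45 within slides, and of 0.35 without THC_Old replicate 1. Oligodendrocyte precursor markers had a median of 0.22 (adjusted p = 0.00918, and adjusted p = 0.380 with an estimated correlation), and Olig1, a transcription factor of this lineage, passed adjusted over the list alone at 0.47 ± 0.14 (adjusted p = 0.0323). Within slides the precursor median was 0.30 and 0.49. The precursor call ended without THC_Old replicate 1 (0.16, adjusted p = 0.177) or control_Old replicate 4 (0.22, adjusted p = 0.0770). Meningeal markers were lower for 11 of 12 genes, with a median of −0.55 (adjusted p = 3.94e-05, and adjusted p = 0.338 with an estimated correlation), among them the transporter gene Slc22a6 at −0.99 ± 0.31 with its other probe at −0.15, and within slides the median was −1.02 and −0.18. Immediate early genes, which neuronal activity induces, were lower for 12 of 13 genes, with a median of −0.44 (adjusted p = 8.82e-05, and adjusted p = 0.380 with an estimated correlation). Fos averaged 8.31 ± 0.41 (SD, n = 5) after THC and 9.13 ± 0.71 (SD, n = 5) after vehicle, Dusp1 differed by −0.60 ± 0.22, and Homer1 by 0.04. The median of this list was −0.72 with the slide as a block, −1.07 and −0.97 within slides, and −0.22 without slide 1, where the call ended (adjusted p = 0.220). The call also ended with the neocortex mean and the midbrain and striatum mean as covariates (−0.18, camera adjusted p = 0.243). Neocortex markers, 9 of 9 lower, had a median of −0.41 (adjusted p = 0.00114, and adjusted p = 0.380 with an estimated correlation), within slides one of −0.63 and −1.06, and without control_Old replicate 5 one of −0.23 (adjusted p = 0.0415).

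Choroid plexus, ependyma, blood and collagen lists also passed at 12 months, and leaving out single arrays ended these calls, in some cases with the median as large as before. Choroid plexus markers were higher for 17 of 19 genes, with a median of 0.47 (adjusted p = 0.00267, and adjusted p = 0.727 with an estimated correlation), and the call ended without THC_Old replicate 1 (0.23, adjusted p = 0.281), THC_Old replicate 5 (0.12, adjusted p = 0.348) or slide 1 (0.15, adjusted p = 0.735). The choroid plexus median was 1.64 with the slide as a block and 1.94 and 2.19 within slides, where THC_Old replicates 1 and 5 were the only old THC arrays. It was 0.74 without THC_Old replicate 2 or 3 and 0.72 without THC_Old replicate 4. Ependyma markers had a median of 0.23 (adjusted p = 0.0226, and adjusted p = 0.461 with an estimated correlation), and within slides one of 0.79 and 0.71. The ependyma call ended without THC_Old replicate 1 (0.15), THC_Old replicate 5 (0.10) or slide 1 (0.16) and with the choroid plexus mean as a covariate (0.03), and also without control_Old replicate 4 (0.24) or control_Old replicate 5 (0.23), where the median kept its size, with adjusted p up to 0.281. All 5 blood genes were lower, with a median of −0.35 (adjusted p = 0.0157, and adjusted p = 0.461 with an estimated correlation), and with the slide as a block it was −0.26 (adjusted p = 0.385) and within slides 0.08 and −1.07. The blood call also ended without control_Old replicate 4 (−0.38), THC_Old replicate 2 (−0.26), THC_Old replicate 4 (−0.28) or control_Old replicate 5 (−0.21), with adjusted p up to 0.223. Collagen and matrix genes had a median of −0.17 (adjusted p = 0.0299, and adjusted p = 0.338 with an estimated correlation), with the fibronectin gene Fn1 passing adjusted over the list alone at −0.65 ± 0.18 (adjusted p = 0.0316), its other probe at 0.0822. With the slide as a block the collagen median was −0.01 (adjusted p = 0.498) and within slides 0.09 and −0.16. The collagen call also ended without THC_Old replicate 4 (−0.10), and without control_Old replicate 4 (−0.22) or control_Old replicate 5 (−0.19), where the median was no smaller, with adjusted p up to 0.158. It was −0.29 without THC_Old replicate 1 and −0.11 without THC_Old replicate 3. In all 10 of 35 lists passed, 11 with the slide as a block, 6 without control_Old replicate 4 and 0 with an estimated correlation. The exact permutation test of list means gave 3 lists under 0.05, at a smallest two-sided p of 0.0159 where 0.00794 is the smallest possible, and 0 after adjustment.

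**Figure D3:**
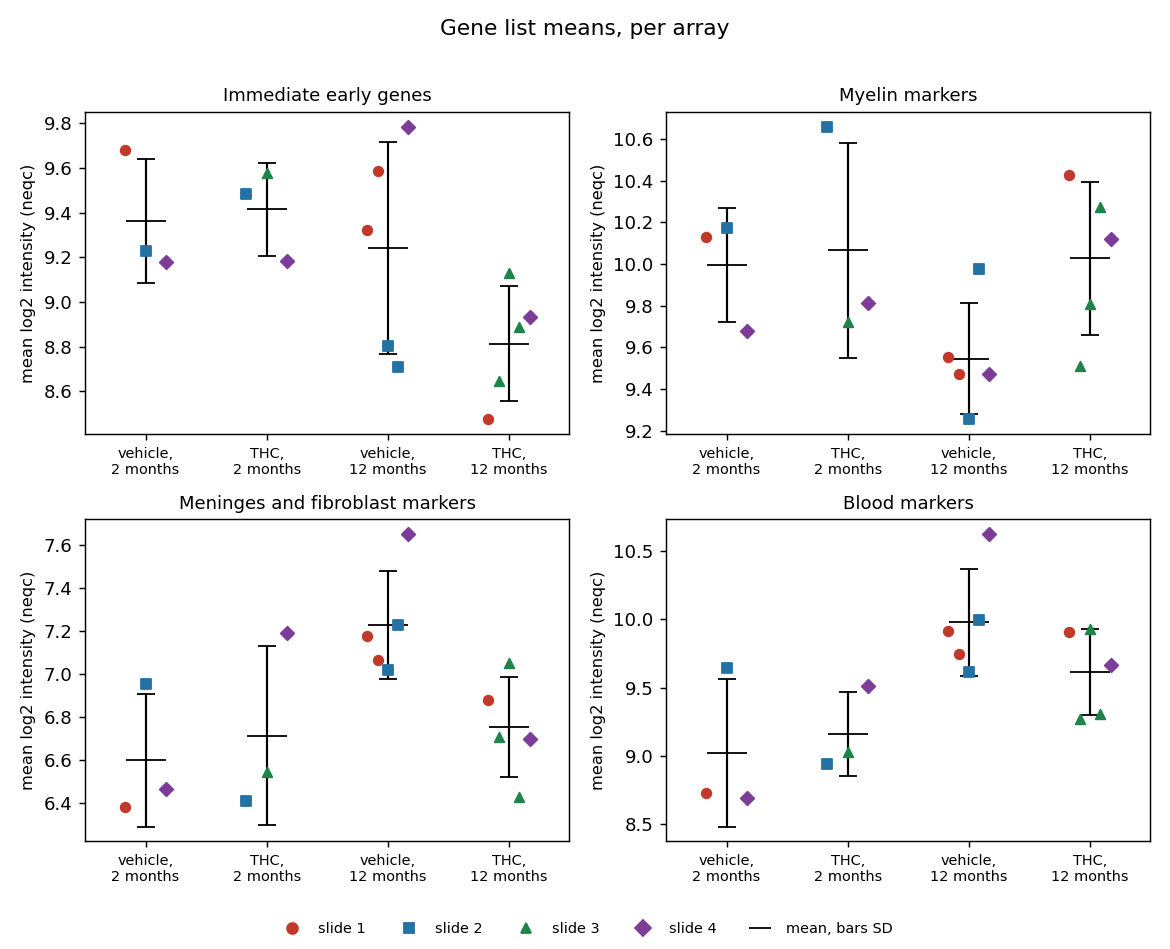
Mean log2 expression of the immediate early, myelin, meningeal and blood genes on each array by age and treatment, with point shapes for the slides and bars for the group mean and SD (3 or 5 arrays). The myelin mean was 9.55 ± 0.27 in vehicle and 10.03 ± 0.37 in THC mice at 12 months.

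The comparison of THC with vehicle at 2 months addressed the effect of the drug in young mice. Htr5b, a serotonin receptor, averaged 6.20 ± 0.22 (SD, n = 3) after THC and 7.20 ± 0.35 (SD, n = 3) after vehicle, a log2 difference of −0.996 ± 0.21 (SE). Islr2 differed by −0.87 ± 0.19, Tmem159 by −0.72 ± 0.16 with its other probe at 0.16, Ralgds, an exchange factor for Ral, by −1.09 ± 0.27, Gal3st3, a sulfotransferase, by −0.87 ± 0.22, Mzt1 by −1.48 ± 0.38 and the myosin gene Myo10 by −0.71 ± 0.19 with its other probe at −0.00994. Slf1 was 1.36 ± 0.31 higher. Without THC_Young replicate 2 Mzt1 was at −0.97. With quantile normalization alone Htr5b and Islr2 were at −0.54, Tmem159 at −0.34, Ralgds at −0.50, Myo10 at −0.25 and Slf1 at 0.64, and the other Gal3st3 probe was at −0.47. Atp2a1, the calcium pump of muscle, was detected on 3 of 3 THC and 0 of 3 vehicle arrays. In the group means of the main processing it was at least 1.62-fold higher, and the chloride channel gene Clcn1 at least 1.17-fold lower. Over the alternatives named for Mocs1 above, the log2 difference ran from 0.30 to 1.10 for Atp2a1 and from −0.67 to −0.22 for Clcn1. Both bounds therefore hold for the main processing alone. Cnr1 differed by −0.02 ± 0.25 (adjusted p = 0.988). The 10 genes with the smallest p had an adjusted p of 0.781. limma called 0 of 22625 probes, with 1384 at an unadjusted p under 0.05, and 0 with the slide as a block, with 2280. Within the 2 slides that held both groups Htr5b differed by −0.94 and −1.20. In an exact two-sided test, 3 against 3 arrays cannot reach a p below 0.1.

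At 2 months thalamus markers were higher after THC, and choroid plexus, ependyma and synaptic genes were lower. Thalamus markers were higher for 9 of 10 genes, with a median log2 difference of 1.12 (adjusted p = 7.74e-05, and adjusted p = 0.687 with an estimated correlation), and Slc17a6 differed by 1.79 ± 0.56. Gbx2, a homeobox gene of the thalamus, was at least 3.75-fold higher in the group mean. Gbx2 was detected on 2 of 3 THC and 0 of 3 vehicle arrays, and its THC values ran from 4.52 to 7.97. The thalamus median was 1.63 with the slide as a block and 1.56 and 1.89 within slides, and the call ended without THC_Young replicate 1 (0.58, adjusted p = 0.0965). The median was 1.68 without THC_Young replicate 2. Synaptic protein genes were lower for 16 of 20 genes, with a median of −0.12 (adjusted p = 0.00737, and adjusted p = 0.687 with an estimated correlation). The kinase gene Camk2a differed by −0.74 ± 0.22 and the neurexin gene Nrxn2 by −0.58 ± 0.20. Of the other 3 Nrxn2 probes 2 went the opposite way at up to 0.12. Within slides the synaptic median was −0.26 and −0.17, and without THC_Young replicate 2 it was −0.24. The synaptic call ended without THC_Young replicate 1 (−0.10, adjusted p = 0.0965) or THC_Young replicate 3 (−0.11, adjusted p = 0.0609). All 19 choroid plexus markers were lower, with a median of −1.04 (adjusted p = 4.00e-05, and adjusted p = 0.735 with an estimated correlation), and without control_Young replicate 2 it was −0.17 (adjusted p = 0.949). Within slides the choroid plexus median had opposite signs, −2.77 and 0.44. Without control_Young replicate 3 it was −1.58. Ependyma markers had a median of −0.72 (adjusted p = 0.0293, and adjusted p = 0.687 with an estimated correlation), and the call ended with the slide as a block (−0.51, adjusted p = 0.124), with the choroid plexus mean as a covariate (−0.24, adjusted p = 0.223) and without control_Young replicate 2 (−0.40, adjusted p = 0.569). It also ended without THC_Young replicate 1 (−0.71, adjusted p = 0.0965) or THC_Young replicate 3 (−0.69, adjusted p = 0.0687), where the median stayed close to its size. Within slides it was −1.55 and −0.15. In all 4 of 35 lists passed, 3 with the slide as a block, 9 without control_Young replicate 1, 1 without THC_Young replicate 1, 2 without control_Young replicate 2 and 0 with an estimated correlation. The exact two-sided permutation of list means gave 0 lists under 0.05, at a smallest possible p of 0.1.

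**Figure D4:**
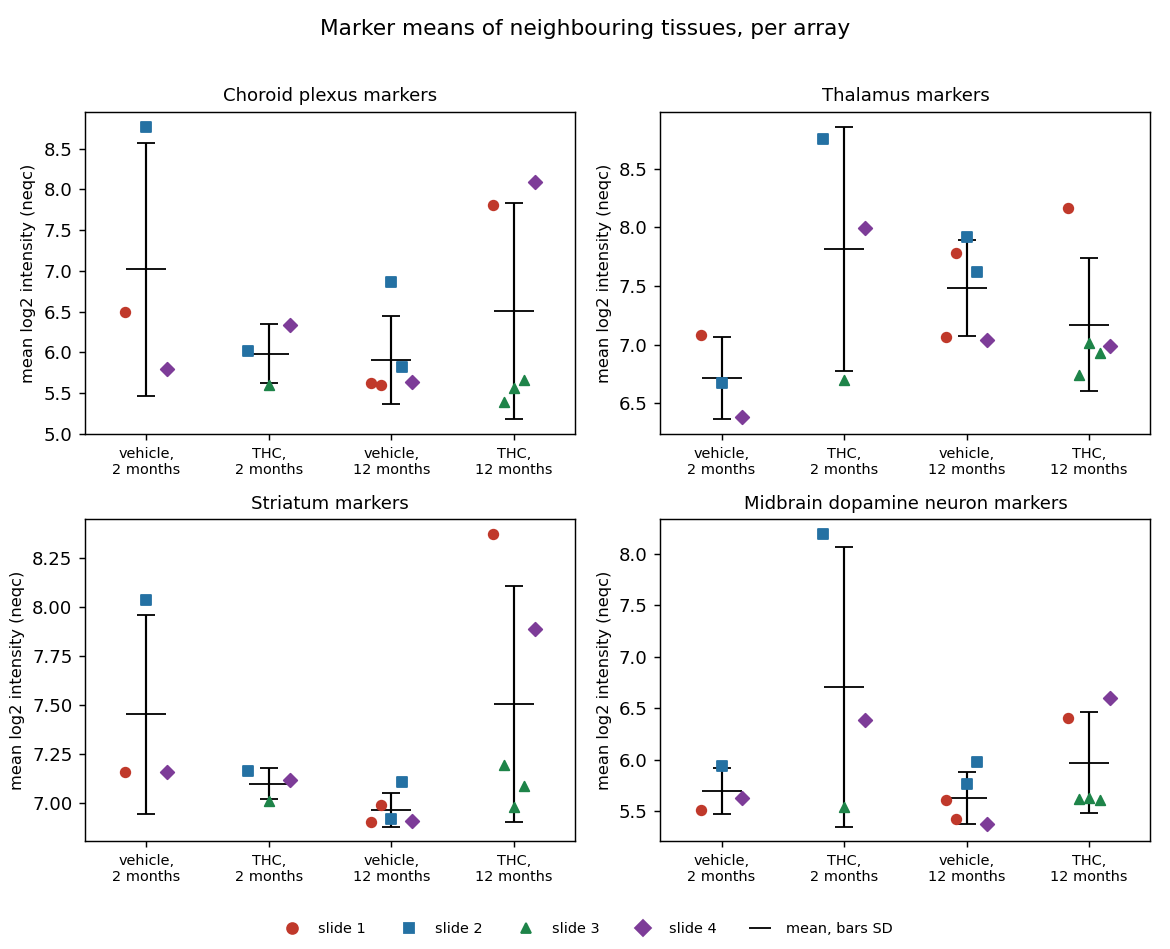
Mean log2 expression of choroid plexus, thalamus, striatum and midbrain dopamine neuron markers on each array by age and treatment, with point shapes for the slides and bars for the group mean and SD (3 or 5 arrays). The choroid plexus mean ran from 5.79 to 8.77 in young vehicle mice and from 5.39 to 8.09 in old THC mice.

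The difference between the THC responses at 12 and 2 months was tested as an interaction. Ntng1 had a response lower at 12 months by a log2 difference of −1.23 ± 0.23, Cxxc4, an inhibitor of Wnt signaling, by −1.04 ± 0.21 with its other probe at −0.16, and Fnbp4 had a response higher by 0.76 ± 0.18 (0.23 with quantile normalization alone) with its other probe at −0.21. Atp2a1 and Dnase1l2 were also among the 5 genes with the smallest p, but Atp2a1 was detected on 0 of 3 young vehicle arrays, and Dnase1l2 on 1 of 3 young vehicle and 1 of 5 old THC arrays, and no size is given. The response of Cnr1 differed by 0.25 ± 0.31 (adjusted p = 0.996), by 0.16 with the slide as a block and by 0.0979 with quantile normalization alone. It was 0.42 without control_Young replicate 1, 0.14 without control_Young replicate 3, 0.13 without THC_Old replicate 2 and 0.0846 without control_Old replicate 4. The 5 genes had an adjusted p of 0.949, and limma called 0 of 22625 probes, with 1179 at an unadjusted p under 0.05, and 0 with the slide as a block, with 2347. For 13 lists the responses differed at the preset correlation, and 0 did with an estimated correlation, where the adjusted p ran from 0.378 to 0.586. The response of the choroid plexus list was 1.61 higher at 12 months (adjusted p = 1.56e-08), that of striatum 0.78 higher (adjusted p = 7.52e-06) and that of thalamus differed by −1.23 (adjusted p = 5.01e-06). The choroid plexus value was 0.64 without control_Young replicate 2 (adjusted p = 0.0191) and the thalamus value −0.76 without THC_Young replicate 1. Immediate early genes had a response of −0.43 relative to 2 months (adjusted p = 0.00656), with Fos at −1.29 ± 0.47, and synaptic genes one of 0.15 (adjusted p = 0.00778), with Camk2a at 0.94 ± 0.27. The immediate early call ended without THC_Young replicate 2 (−0.24, adjusted p = 0.0999) or slide 1 (−0.34, adjusted p = 0.118), and the synaptic call without THC_Young replicate 1 (0.08, adjusted p = 0.0612) or with the slide as a block (0.07, adjusted p = 0.147). The synaptic value was also 0.0824 without control_Young replicate 3 and 0.0948 without THC_Young replicate 3, and the immediate early value −0.23 without THC_Old replicate 1 and −0.28 without control_Old replicate 5. Without THC_Young replicate 2 the count of lists was 7. With the choroid plexus mean as a covariate the immediate early call ended too (−0.22, adjusted p = 0.312), and further calls ended. These were neocortex (−0.40, adjusted p = 0.434), myelin (0.21, adjusted p = 0.301), precursors (0.25, adjusted p = 0.155), CA3 and CA2 cells (0.24, adjusted p = 0.670) and the circadian clock (−0.14, adjusted p = 0.525).

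The comparison of 12 with 2 months in THC mice asked for the effect of age in treated animals. C4b was 1.10 ± 0.19 and C4a 1.14 ± 0.21 higher at 12 months (log2, SE, 5 against 3 arrays), although the lowest of 3 C4b probes was at 0.0635. Mocs1 was 0.66 ± 0.11 higher, the uroplakin gene Upk1b 1.12 ± 0.18 (0.45 with quantile normalization alone) and Nktr, a cyclophilin-related protein, 0.73 ± 0.13. The other 2 Nktr probes went the opposite way, the lowest at −0.19. Their adjusted p lay between 0.148 and 0.158, and limma called 0 of 22625 probes, with 1659 at an unadjusted p under 0.05, and 0 with the slide as a block, with 2903. Within the 2 slides that held both groups C4b differed by 1.06 and 1.35, C4a by 1.25 and 1.51, and Mocs1 by 0.66 and 0.71. Over the alternatives named for Mocs1 above, the adjusted p of Upk1b ran from 0.0174 to 0.165 and that of Mocs1 from 0.0254 to 0.117. Immediate early genes were lower at 12 months, with a median of −0.61 (adjusted p = 7.75e-06, and adjusted p = 0.587 with an estimated correlation), and adjusted over the list alone 4 of them passed, among them Fos at −1.28 ± 0.33 and Egr1 at −0.88 ± 0.27. The median was −0.80 with the slide as a block and ran from −0.78 to −0.28 within slides. Complement and antigen presentation genes were higher, with a median of 0.21 (adjusted p = 0.000326, and adjusted p = 0.587 with an estimated correlation), 2 passed adjusted over the list alone, and within slides the median was 0.20 and 0.0595. Adjusted over the list alone 2 synaptic genes also passed, Syn2 at 0.98 ± 0.25, with its other 2 probes opposite and the lowest at −0.0547, and Cplx2 at 1.13 ± 0.34, while the synaptic list itself did not pass (adjusted p = 0.0590). Choroid plexus markers had a median of 0.56 (adjusted p = 0.00391, and adjusted p = 0.762 with an estimated correlation), and striatum markers one of 0.37 (adjusted p = 0.00523, and adjusted p = 0.677 with an estimated correlation). The first call ended without THC_Old replicate 1 (0.27, adjusted p = 0.105) or THC_Old replicate 5 (0.26, adjusted p = 0.240), and the striatum call without THC_Old replicate 1 (0.19, adjusted p = 0.105). Within slides 3 and 4 the choroid plexus median was −0.0279 and 1.68, that of striatum 0.00294 and 0.89, that of blood 0.54 and 0.14 and that of thalamus 0.13 and −0.72. The signs for choroid plexus and thalamus were opposite. Blood genes had a median of 0.53 (adjusted p = 0.00914, and adjusted p = 0.677 with an estimated correlation) and thalamus markers one of −0.60 (adjusted p = 0.0387, and adjusted p = 0.698 with an estimated correlation). The blood call ended without THC_Young replicate 1 (0.41, adjusted p = 0.101) or THC_Old replicate 3 (0.46, adjusted p = 0.0631). The thalamus median was −0.12 (adjusted p = 0.980) without THC_Young replicate 1, −1.10 without THC_Young replicate 2 and −0.29 (adjusted p = 0.458) with the slide as a block. Its call also ended without THC_Young replicate 3 (−0.55) and without THC_Old replicate 2 (−0.50), 3 (−0.54), 4 (−0.48) or 5 (−0.63), with adjusted p up to 0.101. Without slide 1 the calls of choroid plexus (0.27, adjusted p = 0.151), striatum (0.19, adjusted p = 0.121) and blood (0.44, adjusted p = 0.0560) ended, and with the choroid plexus mean as a covariate that of striatum (0.26, adjusted p = 0.0513). With the slide as a block ependyma (0.51, adjusted p = 0.00845), neocortex (−0.61, adjusted p = 0.00177) and the circadian clock (−0.25, adjusted p = 0.0231) passed, and synaptic genes did with the choroid plexus mean as a covariate (0.0948, adjusted p = 0.0458). In all 6 of 35 lists passed, 8 with the slide as a block and 0 with an estimated correlation. The exact two-sided permutation of list means gave 1 list under 0.05, at 0.0179, and 0 after adjustment.

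Old THC mice were also set against young vehicle mice, to see whether treated older mice still differed from untreated young ones. Mocs1 was higher in the old THC mice by 0.79 ± 0.11 (log2, SE, 5 against 3 arrays, 1.73-fold, adjusted p = 0.0411), at 7.95 ± 0.09 (SD, n = 5) against 7.16 ± 0.11 (SD, n = 3), and on 5 of 5 old arrays it lay above the highest young array. It was the 1 probe that limma called among 22625, with 1014 at an unadjusted p under 0.05, and 2371 with the slide as a block. With the slide as a block Mocs1 differed by 0.85 (adjusted p = 0.0370), and within the 2 slides that held both groups by 0.79 and 0.84. Over the alternatives named for Mocs1 above, its adjusted p ran from 0.00311 to 0.0997. When each of the 16 arrays was left out in turn, it ran from 0.0615 to 0.757. The call ended each time, while the difference stayed between 0.73 and 0.83. The call also ended with the trend and robust variances, with the compared groups alone and without slide 1. As values only, Nktr differed by 0.73 ± 0.13 (adjusted p = 0.377) with 1 of its other 2 probes opposite at −0.12, Nptx2 by −1.08 ± 0.24, C4b by 0.85 ± 0.19 with the lowest of its 3 probes at 0.28, and Htr5b by −0.83 ± 0.19 (each adjusted p = 0.863), the last at −0.47 with quantile normalization alone. Immediate early genes were lower, with a median of −0.61 (adjusted p = 5.56e-06, and adjusted p = 0.524 with an estimated correlation), Fosb at −0.77 ± 0.24 and Egr4 at −0.64 ± 0.26, the call ended without slide 1 (−0.35, adjusted p = 0.111), and within slides the median was −1.26 and −0.18. Blood genes were higher by a median of 0.69 (adjusted p = 0.000173, and adjusted p = 0.524 with an estimated correlation), and the median was 1.29 and 1.18 within slides. This call ended without slide 1 (0.44, adjusted p = 0.0891), and the median was 0.43 without control_Young replicate 3 (adjusted p = 0.0256). Thalamus markers had a median of 0.36 (adjusted p = 0.0448, and adjusted p = 0.618 with an estimated correlation), and without THC_Old replicate 1 it was 0.00042 (adjusted p = 0.347), without THC_Old replicate 2 it was 0.58, and within slides 1.29 and 0.26. That call also ended without control_Young replicate 2 (0.25), control_Young replicate 3 (0.21) or slide 1 (0.21). Without control_Old replicate 2, control_Old replicate 4 or THC_Young replicate 3, arrays of neither group, the median was still 0.36 and the adjusted p at most 0.0552. A further 7 lists passed with the slide as a block, among them choroid plexus (0.68, adjusted p = 0.00435, from −0.42 without the block), striatum (0.47, adjusted p = 0.000783), myelin (0.43, adjusted p = 0.00334) and neocortex (−0.48, adjusted p = 0.0321, from 0.02 without the block). In all 3 of 35 lists passed, 10 with the slide as a block, 5 without control_Young replicate 1 or control_Young replicate 2, 8 without THC_Old replicate 4, 7 without control_Young replicate 3 or THC_Old replicate 5, and 0 with an estimated correlation. The exact two-sided permutation of list means gave 1 list under 0.05, at 0.0357, and 0 after adjustment.

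Whether the drug moved genes against the direction of age was asked with all 22625 probes. Across probes, which are not independent replicates, the effect of age in vehicle mice and that of THC at 12 months correlated at Pearson r −0.470 (Spearman rho −0.420). The 5 old vehicle arrays enter both effects with opposite sign. After the group means were subtracted, 100 random regroupings of the arrays gave a mean r of −0.460, and 53 of them were as low as the observed r. When the old vehicle arrays were divided so that each effect used different ones, 20 such divisions gave a mean r of −0.03 (from −0.23 to 0.29). The 12-month THC arrays correlated with the young vehicle arrays at a mean r of 0.977 ± 0.00382 (SD, n = 5) and the 12-month vehicle arrays at 0.976 ± 0.00403 (SD, n = 5). The difference of 0.000656 had an exact two-sided permutation p of 0.794, where 0.00794 is the smallest possible. Its sign reversed with the slide as a fixed block and when some single arrays were left out.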

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

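Of the tests below, the 6 counts over other groupings of the arrays and the test of immediate early genes with neighbouring tissue as covariates were set before their results were seen, and the 2 choroid plexus tests, the 2 tests of the 31 probes and the slide and THC tests of the immediate early genes only after the result was seen.

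The 5 arrays of each 12-month group were examined for 109 genes and 18 lists, 254 cases in all. In 16 cases 1 array lay far from the others, where chance gives about 1 in 20. The cases are not independent, since they share arrays and some genes are members of the lists, so the tally says little about chance. The value given with each is the gap to the nearest other array over the whole range. Control_Old replicate 3 was the highest for the choroid plexus mean (0.830), at 6.86 against 5.60 to 5.82, for the ependyma mean (0.718) and for the choroid plexus genes Ttr (0.749), Aqp1 (0.896) and Folr1 (0.850). THC_Old replicate 1 was the highest for the thalamus mean (0.810), at 8.17 against 6.74 to 7.01, and for Gbx2 (0.888), Prkcd (0.742) and Atp2a1 (0.735). Control_Old replicate 5 was the highest for Igf2 (0.792) and Bgn (0.722), and control_Old replicate 2 was the lowest for Foxj1 (0.780). THC_Old replicate 5 was the lowest for Lacc1 (0.789), THC_Old replicate 4 for Cp (0.826) and Cspg4 (0.793), and THC_Old replicate 3 for Olig1 (0.783).

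The THC response differed between 12 and 2 months, by the interaction test at the preset correlation, for 13 lists, given as the median difference of the log2 responses. It was 1.61 for choroid plexus, 0.95 for ependyma, 0.78 for striatum, 0.52 for myelin, 0.46 for CA3 and CA2 pyramidal cells, 0.22 for oligodendrocyte precursors and 0.15 for synaptic proteins. It was −1.23 for thalamus, −0.66 for neocortex, −0.56 for meninges, −0.49 for blood, −0.43 for immediate early genes and −0.33 for the circadian clock. No list passed with an estimated correlation (smallest adjusted p = 0.378). Leaving out single arrays ended 8 of these calls, those of neocortex, blood, myelin, oligodendrocyte precursors, CA3 and CA2 pyramidal cells, synaptic proteins, immediate early genes and the circadian clock, with adjusted p up to 0.288 for blood, 0.270 for the circadian clock and 0.213 for myelin and precursors. The arrays were control_Young replicate 2 for neocortex (0.0880), THC_Young replicate 1 for synaptic proteins (0.0612) and THC_Young replicate 2 for immediate early genes (0.0999). For myelin they were control_Young replicate 2 and THC_Young replicates 2 and 3, and for precursors THC_Old replicate 1 and THC_Young replicate 2. CA3 and CA2 cells lost the call without control_Young replicate 1 or 2, THC_Old replicate 1 or THC_Young replicate 2, with adjusted p up to 0.118. The circadian clock lost it without THC_Old replicate 1 or 5, THC_Young replicate 1 or 2, or control_Young replicate 2. Blood lost it without control_Young replicate 1 or 3, THC_Young replicate 2 or 3, THC_Old replicate 2 or 4, or control_Old replicate 5, and also with the slide as a block (−0.40, adjusted p = 0.233). Without slide 1 the calls of blood (−0.49, adjusted p = 0.0923), myelin (0.22, adjusted p = 0.361), CA3 and CA2 cells (0.19, adjusted p = 0.538) and the circadian clock (−0.29, adjusted p = 0.0653) ended. With the choroid plexus mean as a covariate so did those of neocortex (−0.40, adjusted p = 0.434), myelin (0.21, adjusted p = 0.301), precursors (0.25, adjusted p = 0.155), CA3 and CA2 cells (0.24, adjusted p = 0.670) and the circadian clock (−0.14, adjusted p = 0.525). The immediate early call ended both ways, and the synaptic call with the slide as a block. Lists that kept their call moved too, to 0.64 for choroid plexus and 0.51 for ependyma without control_Young replicate 2, to −0.76 for thalamus without THC_Young replicate 1, and to −0.29 without THC_Young replicate 3 and −0.87 without THC_Young replicate 1 for meninges. Over the omission of each array the medians ran from −0.97 to −0.50 for neocortex, from −0.84 to −0.30 for blood, from 0.27 to 0.83 for myelin, from 0.17 to 0.32 for precursors, from 0.30 to 0.71 for CA3 and CA2 cells, from 0.08 to 0.18 for synaptic proteins, from −0.63 to −0.23 for immediate early genes and from −0.44 to −0.18 for the circadian clock, so some calls ended with the median about as large as before.

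The number of called probes was compared with that of other groupings of the same arrays. A count of 0 is equalled by every grouping, so those tests tell nothing about chance. That holds for age in vehicle mice, where 56 of 56 groupings gave as many and the highest other gave 2174, for THC at 12 months with 100 of 100 and 621, for the difference of the THC responses with 100 of 100 and 63, and for age in THC mice with 56 of 56 and 6. The grouping with 2174 probes placed the 3 vehicle arrays of slide 1 together, and the one with 621 set slides 1 and 4 against slides 2 and 3, so both point to the slide structure of the samples. At 2 months 10 of 10 groupings gave at least the 0 probes of the real one, the highest other gave 0, and the groupings are too few for a share under 0.05. For old THC against young vehicle mice 4 of 56 groupings gave at least the 1 probe of the real one and the highest other gave 165, so chance cannot be excluded. The grouping with 165 probes put together THC_Old replicates 1 and 5 and control_Young replicate 2, the 3 of these 8 arrays with the highest choroid plexus means (7.81, 8.09 and 8.77), which points to a structure of the samples. With the slide as a block the count there was 2.

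The choroid plexus list passed in the first 3 comparisons at the preset correlation, and in none of them with an estimated correlation. Spreads within groups were wide. The level of Ttr, one of the most abundant transcripts of choroid plexus, was 12.90 ± 1.56 (SD, n = 3) in young vehicle mice, 11.06 ± 1.95 (n = 3) in young THC, 8.02 ± 3.38 (n = 5) in old vehicle and 10.39 ± 3.64 (n = 5) in old THC mice. Choroid plexus tissue taken along with some hippocampi may account for this, as a hypothesis, since within groups Ttr followed the mean of the other choroid plexus markers over 16 arrays at r 0.754 (permutation p = 0.00014, adjusted 0.00035 over 5 relations, Spearman rho 0.726, permutation p = 0.00179, r 0.765 without the 2 farthest arrays). That r lies between the bounds set for and against this explanation, 0.8 and 0.3, so it stays open. An effect of age or THC stays open too, since the smallest exact two-sided permutation p of the marker mean in the first 3 comparisons was 0.161.

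The 31 probes that differed with THC at 12 months when the slide was a block included Slc6a3 and Drd2, markers of dopamine neurons and striatum. They also held other genes, with Cpm and Klk6 at the smallest p. On the 11 arrays outside the old THC group they followed the mean of midbrain and striatum markers within groups at a median r of 0.637, each turned by the sign of its change, with 31 of 31 positive and 0.472 without the 2 farthest arrays, against a median size of 0.291 for all tested probes. Midbrain and striatal tissue on some arrays is therefore a candidate explanation, as a hypothesis found and tested on the same data. The block fit called no probe with the midbrain and striatum covariate, but also none with the choroid plexus covariate or without THC_Old replicate 1. These fits therefore do not single out midbrain and striatal tissue. The 3 old THC arrays of slide 3 differed from 3 old vehicle arrays of slides 2 and 4 by a median of −0.0318 turned by sign, with 14 of 31 in the direction of the block fit, whose median change was 1.14. Slide 3 holds no old vehicle array, so an effect of THC and a slide difference cannot be told apart there.

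Immediate early genes were lower in old THC mice by a median of −0.44. A difference between slides stays open. With the slide as a block the median was −0.72 (camera adjusted p = 2.73e-06 at the preset and 0.270 at an estimated correlation) and within slides −1.07 and −0.97, but without slide 1 it was −0.22 and the call ended (adjusted p = 0.220). With the neocortex mean and the midbrain and striatum mean as covariates the median was −0.18 and the call ended (camera adjusted p = 0.243 from 8.82e-05 at the preset correlation, where an estimated correlation gave 0.380 without the covariates), so neighbouring tissue on some arrays may account for it, although the neocortex list holds Nr4a2, which neuronal activity also induces. An effect of THC stays open, with an exact two-sided permutation p of 0.127 for the list mean, at 8.81 ± 0.26 (SD, n = 5) in old THC and 9.24 ± 0.47 (SD, n = 5) in old vehicle mice.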

How the results depend on the processing

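The tests without slide 1, those that join the slide block with another choice, and the similarity without the markers of all neighbouring tissues were chosen only after the data were seen, and the other alternatives before. Among 47 gene results the direction and the side of the threshold stayed the same for 45 with quantile normalization alone, where 2 became stronger, and for 46 with the choroid plexus covariate, where 1 became weaker, although sizes changed. Only Mocs1 in old THC against young vehicle mice had a call to lose, so these shares say little about calls. Among 49 list results they stayed the same for 49 with the series matrix values, for 43 with the slide as a fixed block, where 6 became weaker, and for 33 without slide 1, where 16 became weaker. The cause was not tested for the values below, except where fewer arrays were used. For age in vehicle mice the count of 0 probes became 3 with quantile normalization alone and with the series matrix, 2 without a filter, with the strict filter (16877 probes), with the slide as a fixed or random block and at an adjusted p under 0.1, 1 with the trend and robust variances, and 0 to 1 with each array left out. For THC at 12 months it became 31 with the slide as a fixed block and 0 to 0 with each array left out. With the slide block it was 0 when joined with leaving out THC_Old replicate 1, with the choroid plexus covariate or with the midbrain and striatum covariate. For age in THC mice it became 1 with quantile normalization alone, the series matrix, no filter and array weights, and 2 with the slide as a random block. For old THC against young vehicle the count of 1 became 2 with the slide as a fixed block, and 0 with the trend and robust variances, the choroid plexus covariate, without slide 1, with the compared groups alone and with each array left out.

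The counts of passing lists, 13, 10, 4, 13, 6 and 3 in the order of the comparisons, were 0 in each with an estimated correlation. With the choroid plexus covariate they were 2 for THC at 2 months and 7 for the difference of the THC responses, without slide 1 they were 9 and 8 for these and 3 for age in THC mice, and with the slide block 10 for old THC against young vehicle. With each array left out they ran from 7 to 14, from 6 to 12, from 1 to 9, from 7 to 13, from 4 to 8 and from 2 to 8. The difference between old THC and old vehicle arrays in the similarity of old arrays to young vehicle arrays reversed to −0.00142 with the slide as a fixed block (exact two-sided permutation p = 0.270 on values adjusted for the slide) and ran from −0.000933 to 0.00376 with each array left out, reversed without control_Old replicate 2, control_Young replicate 2, control_Young replicate 3 or THC_Old replicate 5. The correlation of the age and THC effects ran from −0.481 to −0.455 over the alternatives and from −0.625 to −0.276 with each array left out. With each array left out the choroid plexus shift with age in vehicle mice ran from −1.53 to 0.0128, reversed without control_Young replicate 2, and Cnr1 after THC at 2 months from −0.19 to 0.0830. With the next brightest probe the difference reversed for Ntng1 (0.0827) after THC at 12 months, Tmem159 (0.16) after THC at 2 months, Fnbp4 (−0.21) in the difference of the THC responses and Nktr (−0.11) with age in THC mice. No paired analysis was possible because the labels give no replicate numbers, and arrays were matched by slide alone, as a block and in differences within slides. Genes near the background of the arrays are limited by signal over background, with at most 45.9% of probes detected on an array.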

Other observations

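The relations between marker lists within groups and the midbrain list below are tests chosen only after the data were seen.

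Lists tied to the drug and to learning had small median log2 differences after THC at 12 months, many of which changed sign within slides. The endocannabinoid list, which holds receptors and enzymes of the system THC acts on, had a median of 0.12 (adjusted p = 0.630), with the degrading enzyme gene Faah at 0.18 ± 0.14. Synaptic proteins had a median of 0.01 (adjusted p = 0.850), neurotrophins 0.02 (adjusted p = 0.630), glutamate receptors 0.09 (adjusted p = 0.456) and GABA-A receptors −0.05 (adjusted p = 0.991). Histone acetylation genes had a median of −0.07 (adjusted p = 0.715), with Kat2b at 0.44 ± 0.23 and Hdac5 at −0.28 ± 0.13. The other Kat2b probe was at 0.16, and 1 of the 3 Hdac5 probes went the opposite way at 0.20. DNA and histone methylation genes had a median of 0.01 (adjusted p = 0.772). Adult neurogenesis had a median of 0.01 (adjusted p = 0.991). Complement and antigen presentation had a median of −0.08 (adjusted p = 0.520), with the class II genes Cd74 at −0.84 ± 0.30 and H2-Ab1 at −0.80 ± 0.30. Interferon response genes had a median of −0.22 (adjusted p = 0.192), inflammation −0.06 (adjusted p = 0.715), microglia 0.02 (adjusted p = 0.850) and astrocytes −0.02 (adjusted p = 0.850). In both slides that held the 2 groups the sign was the opposite for the endocannabinoid list (−0.0957 and −0.0208), GABA-A receptors (0.12 and 0.31), synaptic proteins (−0.0954 and −0.00934) and methylation genes (−0.14 and −0.0685). The slides differed in sign for glutamate receptors (−0.14 and 0.19), adult neurogenesis (−0.19 and 0.0895), complement (−0.20 and 0.13), interferon response (−0.16 and 0.0914), inflammation (−0.36 and 0.28), microglia (−0.11 and 0.0475) and astrocytes (−0.20 and 0.0531). They shared it for neurotrophins (0.0312 and 0.0618) and histone acetylation (−0.12 and −0.0685). These pairs are given from the lower to the higher value.

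Markers of dentate granule cells had a median of 0.47 (adjusted p = 0.0587) after THC at 12 months, those of CA1 pyramidal cells 0.29 (adjusted p = 0.520), of CA3 and CA2 pyramidal cells 0.24 (adjusted p = 0.0893), of inhibitory neurons 0.09 (adjusted p = 0.620), of endothelium and pericytes −0.07 (adjusted p = 0.715) and of thalamus −0.29 (adjusted p = 0.126). Cholesterol synthesis had a median of −0.11 (adjusted p = 0.138), oxidative phosphorylation 0.02 (adjusted p = 0.715), heat shock 0.10 (adjusted p = 0.456), circadian clock −0.07 (adjusted p = 0.536), glucocorticoid response −0.04 (adjusted p = 0.716) and potassium channels 0.03 (adjusted p = 0.168). Within slides, from the lower to the higher value, the medians were 0.19 and 0.70 for dentate granule cells, 0.0198 and 0.0908 for CA1, 0.46 and 0.71 for CA3 and CA2, 0.18 and 0.25 for inhibitory neurons, −0.36 and −0.19 for the circadian clock and −0.15 and −0.11 for cholesterol synthesis. The slides differed in sign for thalamus (−0.0585 and 0.73), endothelium (−0.38 and 0.25), heat shock (−0.31 and 0.0398), glucocorticoid response (−0.11 and 0.12) and potassium channels (−0.0277 and 0.0381), and both were negative for oxidative phosphorylation (−0.0392 and −0.0363). At the preset correlation, CA3 and CA2 cells (0.35, adjusted p = 0.00195), the circadian clock (−0.23, adjusted p = 0.0195) and thalamus (0.71, adjusted p = 0.0299) passed with the slide as a block. With the choroid plexus mean as a covariate dentate granule cells (0.63, adjusted p = 0.0135) and thalamus passed at the preset correlation, thalamus in the other direction (−0.40, adjusted p = 0.0287). Without block or covariate, 0 of 35 lists passed with an estimated correlation in this comparison (smallest camera adjusted p = 0.338).

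Slc6a3, a marker of midbrain dopamine neurons, was detected on 1 of 3 young vehicle, 2 of 3 young THC, 0 of 5 old vehicle and 2 of 5 old THC arrays, and reached 9.53 in young THC and 7.21 in old THC mice. Over 16 arrays and within groups, the striatum mean followed the midbrain mean at Pearson r 0.481 (permutation p = 0.00403, adjusted 0.00672) and Spearman rho 0.771 (permutation p = 0.00195, adjusted 0.00325), with r 0.792 without the 2 farthest arrays. The meninges mean followed the blood mean at r 0.910 (permutation p = 9e-05, adjusted 0.00035, rho 0.776 with permutation p = 0.00125, r 0.869 without the 2 farthest). The myelin and striatum means had r 0.492 (permutation p = 0.0685, adjusted 0.0856, rho 0.535 with permutation p = 0.0492, r 0.346 without the 2 farthest), and Ntng1 and the thalamus mean r 0.288 (permutation p = 0.356, rho 0.147 with permutation p = 0.619, r 0.111 without the 2 farthest). These were 4 of 5 relations computed in this family.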
